A study of Sus scrofa with 5 samples.

How the data were processed

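Bulk RNA sequencing was available for 5 kidney libraries of a pig-to-human xenotransplantation, the second case of the study. The 2 control libraries (replicates 1 and 2) came from untransplanted control kidney at 0 h. The 3 xenograft libraries were 1 biopsy each at 12, 24 and 48 h. Per the labels the organism was pig and the material total RNA from homogenised kidney core biopsies, with libraries depleted of ribosomal RNA. The cell type field of the labels reads as dissociated kidney cells while the protocol field describes core biopsies, and the protocol was followed here. Columns were matched to libraries by the name of their time and replicate.

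The deposited values were raw counts per gene symbol in 2 tables, with 15235 symbols for a pig genome and 59385 for the human genome. Values were whole numbers with a different total in each library, so no normalization by the authors was left in them. The submitters' processing notes give hg38 as the genome build. The aligner, the counting tool, the strand setting, the annotation release and whether reads were mapped to both genomes in competition were not given in the sources used here. A read that fits both genomes can therefore count in either table or in both. Symbols in both tables numbered 14836. Of the pig symbols, 14221 were found in an Ensembl name table and 13818 in a RefSeq gene table of the assembly Sscrofa11.1. No chromosome positions are given, since the tables hold symbols alone. XIST, TSIX and Y-linked genes of the human table were removed before any other step.

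Library totals ranged from 56126783 to 71106149 counts in the pig table and from 13384702 to 19733901 in the human table. Counting error is small at this depth for all but the rarest genes. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. The p-values measure the spread between these libraries alone, since nothing in the labels says that the control libraries came from separate animals and the biopsies came from a single graft. The control libraries differed from each other by more than sampling noise, with a chi-square per degree of freedom of 212 over 12700 genes of the pig table and 13.4 over 17631 genes of the human table.

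Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, and genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 12617 pig and 18396 human genes. Genes were tested with edgeR's quasi-likelihood test with robust prior estimation and Benjamini-Hochberg adjustment at 0.05. Each ± value is an approximate standard error (SE), namely the absolute log2 fold change divided by the square root of the F of that test. Each table gave 5 comparisons. The xenograft biopsies were compared with the controls (3 residual degrees of freedom), where the spread also includes real change between 12 and 48 h. The change per 24 h over 12, 24 and 48 h was fitted within the xenograft (2 residual degrees of freedom). The controls do not enter this slope and add only to the estimate of spread. A fit without a control is therefore no separate check of the slope. With a biopsy left out, the slope joins the remaining biopsies and its spread comes from the control pair alone. Each time was also compared with the controls, where 1 residual degree of freedom comes from the control pair and the lone biopsy is assumed to vary like that pair. The same controls enter the comparisons at each time, so the times were not set against each other by overlap or correlation. On simulated data with 5 libraries, the xenograft comparison recovered 71% of genes changed 2-fold and 97% of genes changed 4-fold in the pig table, with 5.62% of calls false. The shares were 55%, 95% and 3.23% in the human table. The simulation changed 100 genes by each fold. Its false shares rest on 10 false calls for pig genes and 5 for human genes. In the data, 37.5% of pig genes and 35.1% of human genes were called in this comparison. The simulated shares therefore describe the simulated genes and do not give the recovery or the false rate of the real comparison.

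Gene lists were fixed before the data were examined, with 24 lists for the pig table and 17 for the human table. They covered nephron segments, podocytes, endothelium, injury and stress responses, interferon and cytokine responses, complement, matrix, proliferation, fatty acid oxidation, blood cell types, thymus, adipose and muscle tissue, and synthesis of glycan xenoantigens. The human lists for kidney epithelium, endothelium and plasma proteins made in liver were chosen as lists that circulating blood cells should mostly lack, though PECAM1 on the endothelial list is also expressed by platelets and leukocytes. Of 382 pig list members, 322 were in the pig table and 298 were tested, against 289, 289 and 217 for the human lists. A human-table gene near 0 in the controls passes the count filter only when it is high in the biopsies. Counts, medians and camera results of the blood cell lists therefore lean towards a rise, above all where few members were tested. This holds for 3 of 13 dendritic cell, 4 of 15 B cell and 4 of 13 red cell genes. Lists were tested with camera in limma 3.58.1 on log2 CPM (counts per 1000000, prior count 2) at a preset correlation between genes of 0.01, with adjustment over the lists of a table. Camera was run again with an estimated correlation. On simulated data at the preset correlation, 50 of 50 lists of 15 genes raised 2-fold were called, and 3 of 50 unchanged lists. Genes were simulated independently of each other. The check therefore does not cover correlation between genes, on which the list calls below depend. For single times, list medians of the log2 difference from the controls are plotted for the pig table. Members past the threshold are counted over all genes tested and, where the count differs, adjusted over the list alone.

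Named genes followed a rule fixed before the data were examined. It takes the 10 largest log2 fold changes in each direction past the threshold with a mean of at least 5 CPM, 5 in each direction for single times and for the change with time, and up to 4 members per list with a mean of at least 1 CPM. CMAH and PTPRC were always named, while GGTA1 and B4GALNT2 were not analysed here. From the list members taken by the rule, the text mostly prints those that also passed with either control library left out, a choice made after the values were seen.

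In the human table the untransplanted pig kidney was taken to hold no human cell, so its counts measure pig reads assigned to human genes. A gene was over this background in a biopsy with at least 10 counts there and at most 3 in both control libraries together. A predicted background was computed for each gene by multiplying its pig-table count in the biopsy by its ratio of human-table to pig-table counts in the controls. Genes absent from the pig table, or with fewer than 10 counts there in both control libraries together, kept the control level. It was scaled by the TMM-adjusted size of the library in the pig table. A fold against controls at 0 counts is a lower bound, computed against a floor of 3 counts over the control group. With 1 to 3 control counts the ratio is given with its 95% counting interval.

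Alternatives were DESeq2 1.42.0 size factors, no filter on low counts, DESeq2's Wald test, limma-voom, no robust prior, hours on a log2 scale, a 2-fold minimum, scaling of the human table by the pig table, stricter background limits, and leaving out each library in turn. Fits without the 13 mitochondrial genes of the pig table, gene lists with each library left out, and gene families without listed or named genes were added after seeing the data. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.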

Results

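Gene expression was measured by bulk RNA sequencing in kidney core biopsies from a pig kidney xenotransplanted into a human recipient. The 2 control libraries were taken at 0 h from untransplanted control kidney, and 1 xenograft biopsy was taken at each of 12, 24 and 48 h. Reads were counted over a pig genome and over the human genome. The pig-table totals were 65915930 and 71106149 counts in control replicates 1 and 2, and 63234613, 66166387 and 56126783 at 12, 24 and 48 h. The human-table totals were 15055510 and 13384702 in the controls and 19733901, 19183494 and 18765349 in the biopsies. This gave 22.8 and 18.8 human-table counts per 100 pig-table counts in the controls, and 31.2, 29.0 and 33.4 in the biopsies. The 13 mitochondrial genes took 21.9% and 33.4% of pig-table counts in the controls and 12.0%, 14.5% and 11.8% in the biopsies, with COX1 the largest gene in every library.

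How the kidney tissue differed after transplantation was addressed by setting the 3 xenograft biopsies against the 2 controls in the pig table. By their counts below, the proximal tubule and fatty acid oxidation lists were lower in the xenograft, and the lists for tubular injury, endothelial activation, matrix and interferon gamma response were higher at a preset correlation. None of these 6 lists was called with an estimated correlation (adjusted p from 0.346 to 0.526 with an estimated correlation), and matrix genes that rose numbered 2 of 17 without control replicate 2, against 13. LBP, which encodes a protein that binds bacterial lipopolysaccharide, rose 193-fold (log2 fold change 7.60 ± 0.71, SE, 3 biopsies against 2 controls, adjusted p = 0.00112). MMP7, a matrix metalloproteinase, rose 83.0-fold (log2 6.38 ± 0.19, adjusted p = 5.19e-05), and SPP1, encoding osteopontin, rose 74.1-fold (log2 6.21 ± 0.40, adjusted p = 0.000273). S100A2 and ADGRF4 rose 62.7-fold and 47.4-fold, the chemokine gene CXCL11 25.7-fold, and F13A1, encoding a subunit of coagulation factor XIII, 24.6-fold. COL17A1 (52.6-fold), APOA4 (35.3-fold) and MYBL2 (25.5-fold) also rose, but no longer passed without control replicate 1 (adjusted p = 0.0695, 0.149 and 0.0825) or without control replicate 2 (0.085, 0.161 and 0.0999), nor did APOA4 without the 24 h biopsy (0.0523).

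Among genes that fell, FOS was 17.7-fold lower (log2 -4.15 ± 0.34, adjusted p = 0.000692). CCDC60 was 14.7-fold lower, FOSB 14.4-fold and DNAH5, an axonemal dynein gene, 13.5-fold. NOX4, encoding an NADPH oxidase abundant in kidney, was 12.7-fold lower, as was the amino acid transporter gene SLC7A8 at 12.6-fold. HSD17B6 fell 12.5-fold, EGR1 12.3-fold, the lactate transporter gene SLC5A12 12.1-fold and HAO1, a peroxisomal oxidase gene, 12.0-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2332 of 12617 genes were higher and 2402 lower. The counts were 746 and 1069 without control replicate 1, and 467 and 726 without control replicate 2. Of the pig genes taken by the rule for named genes, 34 and 44 values no longer passed without control replicate 1 or 2, and 14 without the 24 h biopsy.

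Of 24 gene lists, 14 were called by camera at a preset correlation, 9 higher and 5 lower. With an estimated correlation 0 of the 24 lists were called, with a smallest adjusted p of 0.346. Proximal tubule genes fell in 17 of 18 members (18 adjusted over the list alone), with a median log2 fold change of -1.96 (camera, adjusted p = 1.11e-08, but adjusted p = 0.431 with an estimated correlation). GATM, a creatine synthesis gene, was 7.18-fold lower (log2 -2.84 ± 0.25), the organic anion transporter gene SLC22A6 6.03-fold lower (log2 -2.59 ± 0.32) and the gluconeogenesis gene FBP1 5.40-fold lower (log2 -2.43 ± 0.19). Fatty acid oxidation genes fell in 13 of 18 members (14 adjusted over the list alone) and rose in 1, CPT1A (median -1.02, camera, adjusted p = 6.98e-05, but adjusted p = 0.526 with an estimated correlation). EHHADH was 3.94-fold lower, HADH 3.72-fold and ACADL 2.79-fold. In fits lacking control replicate 1 or 2, the proximal tubule count was 13 in each fit and the fatty acid oxidation count 8 and 7, and CPT1A did not pass without control replicate 2. The share of counts on mitochondrial genes also differed between the arms, at 21.9% and 33.4% in the controls and at most 14.5% in the biopsies.

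Podocyte genes fell in 5 of 8 members and rose in 1, SYNPO (median -1.13, camera, adjusted p = 0.0371, but adjusted p = 0.526 with an estimated correlation). NPHS1, encoding nephrin of the slit diaphragm, was 4.21-fold lower (log2 -2.08 ± 0.18) and PLA2R1 2.51-fold lower. Collecting duct genes rose in 5 of 11 members (median 0.69, camera, adjusted p = 0.0413, but adjusted p = 0.546 with an estimated correlation), among them the anion exchanger gene SLC4A1 at 2.57-fold (log2 1.36 ± 0.18). Genes of the thick ascending limb and distal tubule went both ways, with 3 of 11 higher and 3 lower (median -0.07, camera, adjusted p = 0.785). CLDN16 rose 3.17-fold, while SLC12A3, the thiazide-sensitive cotransporter gene, was 3.64-fold lower. When control replicate 1 or 2 was dropped, 2 podocyte genes were lower in each fit, 2 and 1 collecting duct genes were higher, and 1 gene of the thick ascending limb list was higher in each fit with 1 and 0 lower. SYNPO did not pass without control replicate 1, control replicate 2 or the 24 h biopsy. The thick ascending limb list had 2 genes higher and 5 lower without the 24 h biopsy (median -0.52), its median was -0.14 without control replicate 2, and it was above 0 without control replicate 1, the 12 h or the 48 h biopsy (0.02, 0.08 and 0.01). SLC12A3 did not pass without either control (adjusted p = 0.059 and 0.0899).

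Tubular injury genes rose in 12 of 14 members (median 2.20, camera, adjusted p = 4.7e-06, but adjusted p = 0.35 with an estimated correlation). Beside SPP1, these included the protease inhibitor gene TIMP1 at 15.2-fold (log2 3.93 ± 0.48), ANXA2 at 12.1-fold (log2 3.60 ± 0.23) and the keratin gene KRT18 at 7.19-fold (log2 2.85 ± 0.28). Endothelial activation and coagulation genes rose in 10 of 15 members and fell in 1 (13 and 1 adjusted over the list alone), with a median of 1.85 (camera, adjusted p = 5.13e-05, but adjusted p = 0.431 with an estimated correlation). The protein C receptor gene PROCR rose 12.4-fold (log2 3.64 ± 0.39), the P-selectin gene SELP 11.02-fold and the urokinase receptor gene PLAUR 7.98-fold. The member that fell was F3, encoding tissue factor, at log2 -0.62. Endothelial cell genes rose in 8 of 14 members (median 0.78, camera, adjusted p = 0.00658, but adjusted p = 0.35 with an estimated correlation), with PECAM1 at 3.68-fold and ESAM at 2.63-fold. Without control replicate 1 or 2 the tubular injury count was 9 and 8 and the endothelial cell count 3 and 2, and the activation count without control replicate 2 was 6. F3 did not pass without control replicate 1, control replicate 2 or the 24 h biopsy.

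Interferon gamma response and antigen presentation genes rose in 11 of 16 members (median 1.24, camera, adjusted p = 7.14e-05, but adjusted p = 0.346 with an estimated correlation). The chemokine genes CXCL9 and CXCL10 rose 11.8-fold (log2 3.56 ± 0.49) and 10.6-fold (log2 3.41 ± 0.15), and the immunoproteasome gene PSMB10 3.78-fold. Type I interferon response genes rose in 7 of 18 members (median 0.80, camera, adjusted p = 0.00658, but adjusted p = 0.549 with an estimated correlation), with ISG15 at 5.07-fold (log2 2.34 ± 0.24) and MX1 at 2.39-fold. The human table held counts for the same genes in the biopsies, from 515 to 5062 for CXCL9 and from 1048 to 8243 for CXCL10, against 1110 to 2874 and 3920 to 4590 in the pig table. NF-kB and cytokine response genes rose in 5 of 15 members and fell in 1 (median 0.58, camera, adjusted p = 0.193), with LIF 5.40-fold higher, the inhibitor gene NFKBIA 2.42-fold higher and CXCL2 3.13-fold lower. With either control replicate 1 or 2 left out, 7 interferon gamma genes rose in each fit, 4 and 2 type I genes, and 3 and 1 NF-kB genes. The NF-kB median was 0.37 without control replicate 2 and without the 12 h biopsy. With the 12 h biopsy left out 3 NF-kB genes fell, and with the 48 h biopsy left out 1 type I gene fell. LIF did not pass without control replicate 2 (adjusted p = 0.0784).

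Leukocyte genes of the pig table did not move together. Myeloid cell genes rose in 7 of 16 members and fell in 1, AIF1 (median 1.61, camera, adjusted p = 0.000197, but adjusted p = 0.526 with an estimated correlation). The scavenger receptor gene CD163 rose 16.2-fold (log2 4.02 ± 0.20), CD68 7.73-fold, CD14 6.64-fold and MSR1 5.25-fold, while PTPRC, the common leukocyte antigen gene, was at log2 -0.29 ± 0.27 and did not pass (adjusted p = 0.428) except without the 48 h biopsy (log2 -0.61, adjusted p = 0.0162). T and NK cell genes fell in 10 of 15 members and rose in 1, NKG7 (median -1.43, camera, adjusted p = 0.00031, but adjusted p = 0.346 with an estimated correlation), with GNLY, encoding granulysin, 17.5-fold lower (log2 -4.13 ± 0.37). The B and plasma cell list had 1 of 7 members higher, CD79A at 1.59-fold (median 0.48, camera, adjusted p = 0.855). CD79A lies next to the ribosomal protein gene RPS19 in the RefSeq annotation of Sscrofa11.1, and its 21282 and 20987 control counts make its value uncertain. It did not pass without control replicate 1 or 2 (adjusted p = 0.178 and 0.124). In fits lacking control replicate 1 or 2, the T and NK count was 3 and 2, and 6 without the 24 h biopsy, while 12 myeloid genes rose without the 12 h biopsy. AIF1 did not pass without control replicate 1, control replicate 2 or the 24 h biopsy, and 2 myeloid genes fell without the 48 h biopsy. The B and plasma cell median was -0.23 without the 12 h and -0.10 without the 48 h biopsy.

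Matrix and fibroblast genes rose in 13 of 17 members (median 1.40, camera, adjusted p = 0.000128, but adjusted p = 0.526 with an estimated correlation), with the tenascin gene TNC at 5.61-fold (log2 2.49 ± 0.39) and the collagen gene COL3A1 at 5.03-fold (log2 2.33 ± 0.57). Proliferation genes rose in 7 of 20 members (9 adjusted over the list alone), with a median of 2.82 (camera, adjusted p = 0.00227, but adjusted p = 0.623 with an estimated correlation). MCM4 and MCM2, parts of the replicative helicase, rose 7.24-fold (log2 2.86 ± 0.55) and 6.40-fold (log2 2.68 ± 0.47). Complement components and regulators rose in 4 of 10 members (median 0.17, camera, adjusted p = 0.388), with the anaphylatoxin receptor gene C5AR1 at 2.69-fold. When control replicate 1 or 2 was dropped, 7 and 2 matrix genes, 1 and 0 proliferation genes and 1 complement gene in each fit rose, and 2 complement genes without the 24 h biopsy. Leaving out the 48 h biopsy took the proliferation median to 1.07 and the complement median to -0.52, with 3 complement genes lower and 4 higher, while the complement median was 0.49 without the 12 h and 0.40 without the 24 h biopsy. COL3A1 (adjusted p = 0.0922 and 0.153), MCM4 (0.0749 and 0.089) and MCM2 (0.0556 and 0.0777) did not pass without control replicate 1 or 2, nor did TNC without control replicate 2 (0.0514).

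Immediate early genes fell in 8 of 13 members (9 adjusted over the list alone) and rose in 2, FOSL1 and MYC (median -1.13, camera, adjusted p = 0.0156, but adjusted p = 0.577 with an estimated correlation). FOSL1, another member of the FOS family, rose 91.8-fold (log2 6.52 ± 0.74), while FOS, FOSB and EGR1 fell. Hypoxia and glycolysis genes rose in 8 of 15 members and fell in 3 (median 0.61, camera, adjusted p = 0.198), with the glycolysis genes HK2 at 7.37-fold higher and PFKFB3 at 4.39-fold higher and the mitophagy gene BNIP3 2.89-fold lower. Heat shock genes rose in 3 of 12 members and fell in 2 (median 0.10, camera, adjusted p = 0.853). The cytosolic chaperone gene HSPA8 was 2.07-fold higher and the mitochondrial chaperone gene HSPE1 1.95-fold lower. Without control replicate 1, 5 immediate early genes fell. Without control replicate 1 or 2, 4 hypoxia genes rose and 1 fell in each fit, and 0 heat shock genes rose in each fit with 1 and 0 lower, while the 24 h biopsy left out gave 5 hypoxia genes and 1 heat shock gene higher. The heat shock median was -0.11 without the 12 h biopsy, with 3 members lower, 0.23 without the 24 h and 0.29 without the 48 h biopsy, and 1 immediate early gene rose without control replicate 2. HSPA8 did not pass without control replicate 1 or 2 (adjusted p = 0.0546 and 0.0966), nor HSPE1 without control replicate 2 (0.0518).

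Small lists of other tissues and of glycan synthesis were not called. Adipose and skeletal muscle genes fell in 3 of 5 members (median -1.11, camera, adjusted p = 0.198), among them the lipid droplet gene PLIN4 at 6.51-fold lower. Thymus genes fell in 2 of 3, DNTT and TOX (median -1.23, camera, adjusted p = 0.198), and 1 of 2 red cell genes rose, HBB at 4.77-fold (median 0.54, camera, adjusted p = 0.845). Glycan xenoantigen synthesis genes rose in 3 of 5 members (median 0.57, camera, adjusted p = 0.0619), among them CMAH, which makes N-glycolylneuraminic acid, at 2.41-fold (log2 1.27 ± 0.36, adjusted p = 0.0313). With either control replicate 1 or 2 left out, 1 adipose gene fell in each fit, 0 thymus genes in each fit, 0 red cell genes rose in each fit, and 1 and 0 glycan genes rose. The red cell median was 0.32 without control replicate 1. Without the 24 h biopsy 1 adipose gene and 0 thymus genes fell, and 1 red cell gene and 0 glycan genes rose. Without the 48 h biopsy 1 thymus gene and 1 red cell gene fell. Without the 12 h biopsy 1 adipose gene rose and 2 fell. CMAH did not pass without control replicate 2 (adjusted p = 0.207) or without the 24 h biopsy (0.0534), nor HBB without control replicate 1 or 2 (0.0924 and 0.0838).

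**Figure D1:**
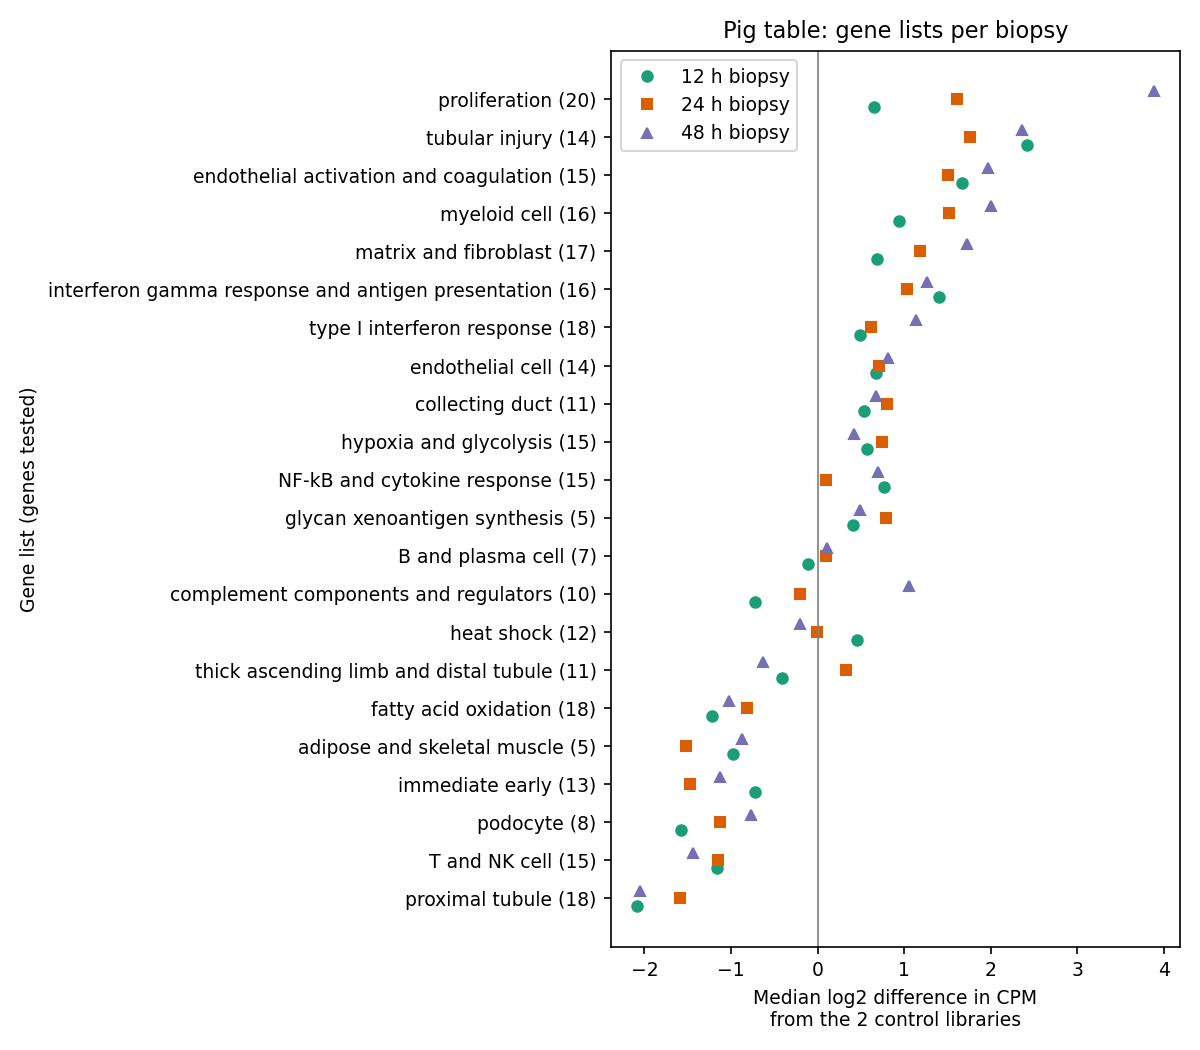
Median log2 difference in CPM (counts per 1000000) from the 2 control libraries (x axis) of the 22 pig gene lists with at least 5 genes tested (y axis, number of genes in brackets), with 1 point per biopsy and no error bar because each time has 1 library. The proliferation median stands at 0.65, 1.61 and 3.89 at 12, 24 and 48 h, and the proximal tubule median at -2.09, -1.59 and -2.06.

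How expression changed within the xenograft was addressed by a slope over 12, 24 and 48 h in the pig table. Of 20 proliferation genes 19 rose with time, though the list was not called with an estimated correlation (adjusted p = 0.436 with an estimated correlation). TOP2A, encoding a topoisomerase of dividing cells, rose 10.1-fold per 24 h (log2 3.34 ± 0.21, adjusted p = 0.000381), PBK 9.73-fold, PCLAF 8.88-fold, CDK1, the kinase that drives mitosis, 8.02-fold and the mitotic kinesin gene KIF11 7.26-fold. APOA4 fell 7.46-fold per 24 h (log2 -2.90 ± 0.16, adjusted p = 0.000229), the chemokine gene CCL16 4.50-fold, CYP2A19 4.02-fold, the transthyretin gene TTR 3.73-fold and the stanniocalcin gene STC1 3.29-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 423 of 12617 genes rose and 124 fell. Without the 12, 24 or 48 h biopsy the counts were 693 and 353, 1748 and 1059, and 995 and 611. In these fits the spread comes from the control pair alone. CYP2A19 did not pass without the 48 h biopsy (log2 -0.45, adjusted p = 0.48).

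Proliferation genes rose with time in 19 of 20 members (20 adjusted over the list alone), with a median log2 change of 1.63 per 24 h (camera, adjusted p = 5.67e-20, but adjusted p = 0.436 with an estimated correlation). Complement genes rose in 6 of 10 (8 adjusted over the list alone; median 1.0, camera, adjusted p = 1.2e-05, but adjusted p = 0.436 with an estimated correlation) and matrix genes in 6 of 17 (9 adjusted over the list alone; median 0.67, camera, adjusted p = 1.2e-05, but adjusted p = 0.747 with an estimated correlation). Myeloid cell genes rose in 4 of 16 (7 adjusted over the list alone; median 0.39, camera, adjusted p = 9.82e-05, but adjusted p = 0.747 with an estimated correlation) and type I interferon genes in 2 of 18 (9 adjusted over the list alone; median 0.41, camera, adjusted p = 0.000833, but adjusted p = 0.747 with an estimated correlation). The podocyte list was also called higher with time, at 1 of 8 members (3 adjusted over the list alone; median 0.37, camera, adjusted p = 0.041, but adjusted p = 0.747 with an estimated correlation). Lists called lower with time were heat shock (median -0.24) and hypoxia (median -0.25), each with 1 member lower (2 and 3 adjusted over the list alone; camera, adjusted p = 0.00302, but adjusted p = 0.436 with an estimated correlation). Immediate early genes (median -0.35, camera, adjusted p = 0.0036, but adjusted p = 0.747 with an estimated correlation) and proximal tubule genes (median -0.17, camera, adjusted p = 0.0197, but adjusted p = 0.904 with an estimated correlation) were called lower with 1 member past the threshold each (1 and 3 adjusted over the list alone). The 14 other lists were not called.

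Each biopsy was also set against the controls, to describe what stood out at each time. The ± values at single times rest on the control pair, pooled over genes, and do not measure spread between biopsies. At 12 h LBP was 143-fold higher (log2 7.16 ± 0.20), SPP1 104-fold (6.71 ± 0.27), MMP7 90.7-fold, S100A2 82.8-fold and APOA4 78.2-fold. ETNPPL, encoding a lyase of phosphoethanolamine, was 61.3-fold lower at 12 h (log2 -5.94 ± 0.22), the nuclear receptor gene NR1I3 20.8-fold, SLC7A8 19.5-fold, the apelin receptor gene APLNR 19.2-fold and the cilia gene CFAP74 18.7-fold. At 24 h LBP was 110-fold higher (log2 6.78 ± 0.20), MMP7 79.3-fold, SPP1 56.8-fold, S100A2 53.2-fold and ADGRF4 44.2-fold, and DNAH5 was 25.6-fold lower (log2 -4.68 ± 0.26), ETNPPL 18.1-fold, CCDC60 17.9-fold, FOS 17.7-fold and HSD17B6 17.6-fold. At 48 h LBP was 326-fold higher (log2 8.35 ± 0.20), COL17A1 113-fold, MMP7 78.8-fold, ADGRF4 65.7-fold and SPP1 61.1-fold, and CCL16 was 30.8-fold lower (log2 -4.94 ± 0.20), FOS 25.8-fold, CYP2A19 23.8-fold, SLC5A12 19.0-fold and the amino acid transporter gene SLC7A13 14.9-fold. Genes past the threshold numbered 3600 higher and 3557 lower at 12 h, 3047 and 2937 at 24 h, and 3383 and 3120 at 48 h. These counts take the spread from the control pair alone, and DESeq2's Wald test gave 2410 and 2539, 1964 and 1902, and 2268 and 2218.

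Whether human cells were present in the xenograft was addressed with the human table, in which the untransplanted kidney gives the background of pig reads assigned to human genes. Blood cell genes nearly absent from the controls had many counts in every biopsy. Genes over the background numbered 864 at 12 h, 669 at 24 h and 1123 at 48 h, and 581 were over it in each of the 3 biopsies. Their summed counts were 1545, 1030 and 2512 per 1000000 pig-table counts, or 0.495%, 0.355% and 0.751% of the human table. S100A9, a calcium-binding protein gene of neutrophils and monocytes, had 1 count in each control and 7389, 4550 and 5107 counts in the biopsies, a ratio of 3650 (95% counting interval 1010 to 30100). The human mitochondrial gene MT-ND2 was at 0 in the controls and at least 981-fold higher in the xenograft, and MT-CO3 had a ratio of 4100 (1140 to 33900). C1orf162 was at least 312-fold higher, APOL6 at least 305-fold, the lymphocyte GTPase gene GIMAP4 at least 279-fold, the lysosomal protease gene CTSD at least 251-fold, IFI16 at least 235-fold, CD48 at least 230-fold and APOL3 at least 228-fold. APOL3 did not pass the test without control replicate 1 or 2 (adjusted p = 0.0523 and 0.0543).

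By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3545 of 18396 human-table genes were higher in the xenograft and 2915 lower. In fits lacking control replicate 1 or 2, the counts were 1893 and 1630 or 1570 and 1327. Genes that fell included SLC16A4 (19.9-fold lower), FOS (18.2-fold), CTD-2026G22.1 (17.7-fold), TMEM233 (16.7-fold), HAO1 (16.6-fold), DNAH5 (16.5-fold), FOSB (15.6-fold), EGR1 (15-fold), NOX4 (14.1-fold) and SLC5A12 (13.9-fold). Control counts were taken as pig reads assigned to human genes. A gene lower than the controls in this table, here or at single times, is therefore read as a fall of that pig background. FOSB did not pass without control replicate 1 (adjusted p = 0.0592) or without the 24 h biopsy (0.115). Scaled by the pig table, the median of all human-table genes lay at a log2 fold change of 0.35, and 5443 genes were higher and 1712 lower.

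Of 17 human lists, 14 were called, 13 higher and 1 lower, and with an estimated correlation 0 of 17 were called, with a smallest adjusted p of 0.257. Neutrophil genes rose in 17 of 18 members (18 adjusted over the list alone), with a median log2 fold change of 7.85, or 6.32 with genes at 0 in the controls at their bound (camera, adjusted p = 5.15e-15, but adjusted p = 0.257 with an estimated correlation). Members with over 3 counts in the controls, which the pig kidney background also reaches, numbered 3 for the neutrophil, 12 for the monocyte and macrophage, 5 for the NK and 9 for the T cell list. Summed neutrophil counts were 0.394 and 0.239 per 1000000 pig-table counts in the controls and 265, 161 and 211 in the biopsies. S100A9, which monocytes also express, gave 7389 of 16763, 4550 of 10636 and 5107 of 11830 counts of that sum. S100A8 gave 4287, 2486 and 2586. The sum therefore does not separate neutrophils from monocytes. The formyl peptide receptor gene FPR2 was at least 105-fold higher and S100A12 at least 78-fold. Monocyte and macrophage genes rose in 18 of 19 members (19 adjusted over the list alone; median 6.44, the same at the bound, camera, adjusted p = 4.36e-14, but adjusted p = 0.257 with an estimated correlation), with LYZ, encoding lysozyme, at 5 control counts and 10253, 7356 and 12240 in the biopsies. Their summed counts were 15.8 and 15.2 per 1000000 pig-table counts in the controls and 554, 470 and 916 in the biopsies. Phagocytosis and scavenging genes, 6 of them also on the monocyte and macrophage list, rose in 12 of 15 (13 adjusted over the list alone; median 4.79, camera, adjusted p = 1.73e-07, but adjusted p = 0.257 with an estimated correlation). The predicted background made at most 19.1% of the monocyte and macrophage sum and 38.0% of the phagocytosis sum in a biopsy.

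NK cell and cytotoxic genes rose in 13 of 16 members (median 7.79, or 5.25 at the bound, camera, adjusted p = 4.5e-09, but adjusted p = 0.286 with an estimated correlation). GNLY was at least 106-fold higher, NKG7 and KLRD1 at least 88.7-fold each, and FCGR3A had a ratio of 2070 (573 to 17100). T cell genes rose in 5 of 10 members (7 adjusted over the list alone; median 2.26, camera, adjusted p = 0.00379, but adjusted p = 0.387 with an estimated correlation). CD4, which monocytes also express, had 1 control count and 306, 238 and 728 in the biopsies, and CD247, a chain of the T cell receptor complex that NK cells also express, had a ratio of 43.9 (12.0 to 365). CD4 gave 306 of 551, 238 of 475 and 728 of 1394 counts of the T cell sum. Genes closer to T cells, picked after their values were seen, had few counts at 12, 24 and 48 h, with 1, 0 and 18 for TRAC, 3, 3 and 8 for CD3D, 2, 3 and 9 for CD3G and 16, 11 and 46 for CD3E, against 2, 0, 14 and 6 in the controls together. B cell genes rose in 2 of 4 members (median 4.35, or 3.83 at the bound, camera, adjusted p = 0.0276, but adjusted p = 0.286 with an estimated correlation), one of them the complement receptor gene CR2 with a ratio of 28.5 (7.73 to 237). Summed counts per 1000000 pig-table counts in the biopsies were 69.7, 53.7 and 125 for the NK list, 8.71, 7.18 and 24.8 for the T cell list and 1.69, 1.78 and 4.10 for the B cell list. FCGR3A, which monocytes and macrophages also express, gave 2961 of 4404, 2376 of 3550 and 4339 of 6998 counts of the NK sum. Dendritic cell genes rose in 2 of 3 (median 8.33, or 4.32 at the bound, camera, adjusted p = 0.0274, but adjusted p = 0.286 with an estimated correlation), with CLEC10A at least 114-fold higher, and plasma cell genes in 1 of 8, DERL3 (median 0.74, camera, adjusted p = 0.218). Only 3 of the 13 dendritic cell members were tested. Untested members had few counts at 12, 24 and 48 h, among them 0, 0 and 6 for CLEC9A and 0, 0 and 2 for CLEC4C. The 2 genes that rose therefore do not stand for the list. DERL3 had 309, 335 and 195 counts against a predicted background of 299.3, 287.7 and 174.5. The predicted background made 86.2%, 81.4% and 67.6% of the plasma cell sum at 12, 24 and 48 h, and 117.6%, 107.2% and 100.3% of the dendritic cell sum. TCF4 alone had 1146 of 1472, 1581 of 1763 and 1719 of 2254 dendritic cell counts, and over members with at least 10 counts the median background was 0.0% at each time, against 71.1%, 47.6% and 70.2% for the plasma cell list. It made at most 3.4% of the NK, 18.3% of the T cell and 22.3% of the B cell sum. The T cell count was 3 and 2 without control replicate 1 or 2, the T cell median was 1.31 without the 48 h biopsy, 3 B cell genes rose without the 24 h biopsy, the plasma cell median was 0.42 without control replicate 2, and DERL3 did not pass without either (adjusted p = 0.092 and 0.0509).

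Red cell genes rose in 3 of 4 members (4 adjusted over the list alone; median 3.35, camera, adjusted p = 0.00144, but adjusted p = 0.257 with an estimated correlation), with the hemoglobin gene HBB 111-fold higher (log2 6.79 ± 0.34). Another of the 3, SLC4A1, is also on the pig collecting duct list, and its 549, 762 and 699 counts at 12, 24 and 48 h lay at or below the predicted pig background of 576, 839.8 and 700.1. It did not pass without control replicate 1 (adjusted p = 0.0747). The predicted background made 13.5%, 23.9% and 21.7% of the summed red cell counts. Platelet genes rose in 7 of 8 (8 adjusted over the list alone; median 4.72, or 2.71 at the bound, camera, adjusted p = 0.00032, but adjusted p = 0.257 with an estimated correlation), with the chemokine gene PPBP at a ratio of 126 (22.4 to 4990). The summed platelet counts were mostly those of SPARC, which kidney also expresses, and the predicted background made 98.9%, 100.5% and 96.0% of that sum at 12, 24 and 48 h, with a median of 4.4%, 4.5% and 21.1% over members with at least 10 counts. For the neutrophil list it made 0.2%, 0.3% and 0.4%. The platelet count was 3 without either control. PTPRC, the common leukocyte antigen gene, rose 17.6-fold in the human table (log2 4.14 ± 0.39, adjusted p = 0.000203).

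Type I interferon response genes rose in 18 of 19 members (19 adjusted over the list alone; median 3.40, camera, adjusted p = 2.87e-09, but adjusted p = 0.286 with an estimated correlation). SIGLEC1, a macrophage lectin gene, was at least 89.6-fold higher, XAF1 at least 60.4-fold, and IFIT2 108-fold. Interferon gamma response and antigen presentation genes rose in 19 of 22 (21 adjusted over the list alone; median 4.55, camera, adjusted p = 8.38e-11, but adjusted p = 0.286 with an estimated correlation). HLA-DPA1, a class II gene, had 4 control counts and 2117, 1921 and 6342 in the biopsies. CXCL9 and CXCL10 rose 329-fold and 296-fold, though neither passed without control replicate 1 (adjusted p = 0.117 and 0.0705) or 2 (0.116 and 0.0826), nor CXCL9 without the 24 h biopsy (0.0645). Inflammatory cytokine genes rose in 9 of 13 (11 adjusted over the list alone; median 4.54, or 4.03 at the bound, camera, adjusted p = 3.92e-05, but adjusted p = 0.286 with an estimated correlation), with CCL3 at least 40.4-fold and IL1B at least 23.7-fold higher. The predicted background made 62.3%, 60.1% and 44.5% of the summed cytokine counts at 12, 24 and 48 h, and at most 15.2% of the type I and 25.4% of the interferon gamma sum. NFKBIA gave most of the cytokine background, with 2197.9, 1510.2 and 1702.7 counts, and the median over cytokine genes with at least 10 counts was 3.0%, 2.9% and 1.4%. When control replicate 1 or 2 was dropped, the type I count was 11 and 9, and the interferon gamma count 12 in each fit.

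**Figure D2:**
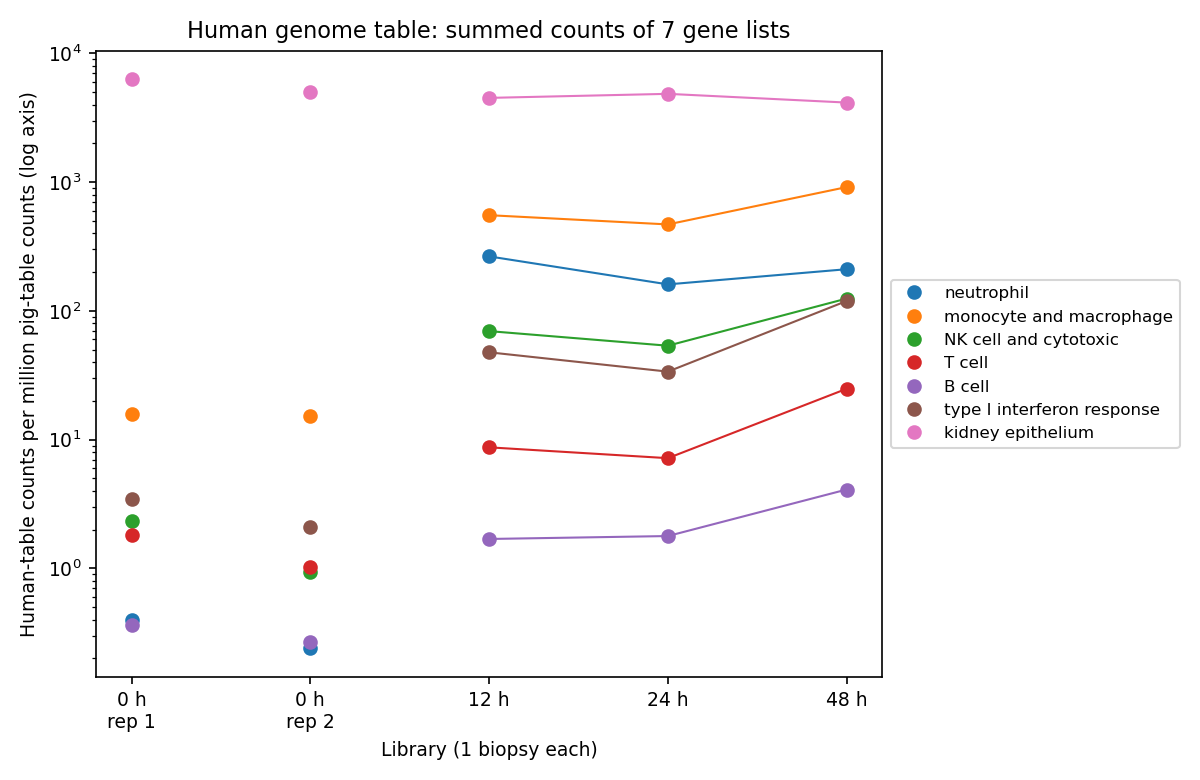
Summed human-table counts per 1000000 pig-table counts (y axis, log scale) of 7 gene lists in each of the 5 libraries (x axis, evenly spaced), with points for libraries and lines joining the 3 biopsies. The neutrophil sum goes from at most 0.394 in the controls to 265, 161 and 211 in the biopsies, while the kidney epithelium sum goes from 6306 and 5055 to 4515, 4854 and 4152. S100A9, which monocytes also express, gave 7389 of 16763, 4550 of 10636 and 5107 of 11830 counts of the neutrophil sum.

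**Figure D3:**
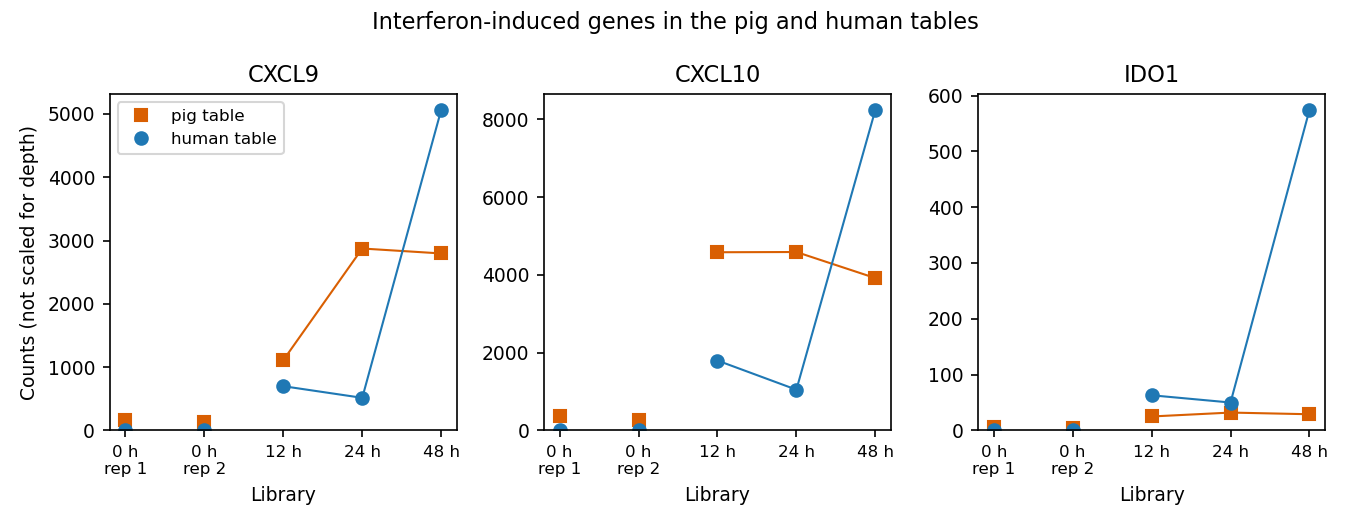
Counts, not scaled for depth (y axis), of CXCL9, CXCL10 and IDO1 in the pig and human tables in each of the 5 libraries (x axis, evenly spaced), with lines joining the 3 biopsies. Human-table CXCL10 goes from 1048 counts at 24 h to 8243 at 48 h, while pig-table CXCL10 goes from 4590 to 3920.

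Lists of kidney epithelium, endothelium and liver plasma proteins were set against the predicted pig background. Kidney epithelium genes had 6306 and 5055 counts per 1000000 pig-table counts in the controls, and fell in 14 of 20 members in the xenograft (median -1.49, camera, adjusted p = 8.73e-07, but adjusted p = 0.286 with an estimated correlation), with GATM 7.96-fold lower. Endothelial cell genes rose in 3 of 12 (2 adjusted over the list alone; median 0.56, camera, adjusted p = 0.117), with PECAM1, which platelets and leukocytes also express, at 6.16-fold. PECAM1 had 1281, 1143 and 1377 counts against a predicted background of 594.4, 663.7 and 583.6, so blood cell genes are not absent from this list. Plasma protein genes of liver rose in 2 of 9 and fell in 3 (median 0.03, camera, adjusted p = 0.32), with APOA1 3.24-fold higher and SERPINC1 3.93-fold lower. Over the 20 kidney epithelium genes the median predicted background was 95.8%, 96.6% and 95.9% of the counts at 12, 24 and 48 h. Their summed background exceeded the counts because genes without pig-table counts are held at the control level, above all MIOX at 38214 predicted against 5138 counted at 12 h. The predicted background made at least 85.9% of the endothelial sum and 91.1% of the plasma protein sum in each biopsy. Proliferation genes rose in 5 of 17 (2 adjusted over the list alone; median 2.67, camera, adjusted p = 0.00942, but adjusted p = 0.522 with an estimated correlation), with MCM2 at 6.36-fold, and the predicted background made 67.2%, 65.7% and 62.4% of their summed counts in the biopsies (median over members with at least 10 counts 81.5%, 83.8% and 67.5%). Without control replicate 1 or 2, 1 and 0 proliferation genes rose, against 2 without the 24 h biopsy and 8 without the 48 h biopsy, where their median was 0.96. Leaving out the 48 h biopsy also gave 2 kidney epithelium genes higher and a plasma protein median of -0.75, with 3 members higher and 4 lower, while that median was -0.13 without control replicate 2 and above 0 in the other fits, with 2 or 3 members lower. The endothelial count was 1 without control replicate 2, the count of plasma protein genes that rose was 1 without either control, and MCM2 did not pass without control replicate 2 (adjusted p = 0.0643).

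With time in the xenograft, 15 of 17 proliferation genes and 6 of 22 interferon gamma genes of the human table rose. Neither list was called with an estimated correlation (adjusted p = 0.332 and 0.345 with an estimated correlation). NCAPG, a condensin gene, rose 11.1-fold per 24 h (log2 3.48 ± 0.30, adjusted p = 0.000253), the cyclin gene CCNB1 10.5-fold, BUB1B 9.54-fold, TOP2A 9.35-fold and PBK 8.88-fold. APOA4 fell 6.77-fold per 24 h (log2 -2.76 ± 0.25, adjusted p = 0.000404) and STC1 3.39-fold. The paralogs CYP2A7, CYP2A6 and CYP2A13 fell 4.46-fold, 3.96-fold and 3.72-fold, and reads shared between them may make each value uncertain. Pig-table genes changed at like rates per 24 h, at log2 -2.01 for CYP2A19, -2.90 for APOA4, -1.72 for STC1, 3.34 for TOP2A and 3.28 for PBK. Pig reads assigned to human genes are therefore a candidate for these human-table changes. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 170 of 18396 genes rose and 36 fell. Without the 12, 24 or 48 h biopsy the counts were 734 and 228, 751 and 261, and 274 and 88, with the spread taken from the control pair alone. Without the 48 h biopsy CCNB1 (adjusted p = 0.932), STC1 (0.104) and CYP2A7, CYP2A6 and CYP2A13 (0.707, 0.969 and 0.907) did not pass. Leaving out control replicate 1 left the slopes of these paralogs nearly the same, at log2 -2.18, -2.01 and -1.90, because the controls do not enter the slope.

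Interferon gamma genes of the human table rose with time in 6 of 22 members (19 adjusted over the list alone; median 0.87, camera, adjusted p = 8.11e-12, but adjusted p = 0.345 with an estimated correlation) and type I interferon genes in 2 of 19 (17 adjusted over the list alone; median 0.94, camera, adjusted p = 8.11e-12, but adjusted p = 0.345 with an estimated correlation). IDO1, which breaks down tryptophan, had 63, 50 and 574 human-table counts at 12, 24 and 48 h and 25, 32 and 29 pig-table counts. T cell genes (median 0.97, camera, adjusted p = 1.82e-06, but adjusted p = 0.345 with an estimated correlation), NK genes (0.59, adjusted p = 9e-05, but adjusted p = 0.385 with an estimated correlation) and B cell genes (1.0, adjusted p = 0.015, but adjusted p = 0.332 with an estimated correlation) were called higher with 0 of 10, 1 of 16 and 0 of 4 members past the threshold, or 7, 5 and 2 adjusted over the list alone. Monocyte and macrophage genes rose in 4 of 19 (8 adjusted over the list alone; median 0.55, camera, adjusted p = 0.00015, but adjusted p = 0.332 with an estimated correlation) and phagocytosis genes in 3 of 15 (6 higher and 1 lower adjusted over the list alone; median 0.40, camera, adjusted p = 0.00589, but adjusted p = 0.332 with an estimated correlation). Neutrophil genes (median -0.37, camera, adjusted p = 9e-05, but adjusted p = 0.332 with an estimated correlation) and platelet genes (median -0.61, camera, adjusted p = 0.00225, but adjusted p = 0.332 with an estimated correlation) were called lower, with 0 members past the threshold in either list. Proliferation genes rose in 15 of 17 (17 adjusted over the list alone; median 2.62, camera, adjusted p = 7.06e-27, but adjusted p = 0.332 with an estimated correlation). The 10 lists called here were 6 without the 48 h biopsy.

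Each biopsy was set against the controls in the human table too. MT-ND2, at 0 in the controls, had 1900, 1661 and 3313 counts at 12, 24 and 48 h. C1orf162, also at 0 in the controls, had 724, 490 and 974 counts, APOL6 598, 397 and 1140, GIMAP4 481, 439 and 1034, and CTSD 475, 414 and 871. At 12 h ETNPPL was 80.0-fold lower, NR1I3 32.5-fold, CTD-2026G22.1 27.7-fold, PLPPR1 24.1-fold and RAB3C 18.4-fold. At 24 h TMEM233 was 29.4-fold lower, DNAH5 28.9-fold, SLC16A4 22.0-fold, FOSB 18.9-fold and HAO1 17.8-fold. At 48 h FOSB was 49.5-fold lower, CYP2A7 39.3-fold, CYP2A6 34.3-fold, CYP2A13 26.5-fold and FOS 25.1-fold. Genes past the threshold numbered 3936 higher and 3432 lower at 12 h, 3332 and 2361 at 24 h, and 4180 and 3206 at 48 h, with the spread taken from the control pair. DESeq2's Wald test gave 1910 and 1845, 1490 and 1142, and 2147 and 1719.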

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

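The tests of explanations in this part were chosen after the results were seen, and the tests of change with time were planned.

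Each result here differed between time points of the xenograft, by the test of the change per 24 h. In the pig table the median log2 change per 24 h was -0.17 for proximal tubule, 0.37 for podocyte, -0.35 for immediate early, -0.24 for heat shock, -0.25 for hypoxia and glycolysis, 0.41 for type I interferon response, 1.63 for proliferation, 1.0 for complement, 0.67 for matrix and 0.39 for myeloid cell genes. In the human table it was -0.37 for neutrophil, 0.55 for monocyte and macrophage, 0.97 for T cell, 0.59 for NK cell, 1.0 for B cell, -0.61 for platelet, 0.94 for type I interferon, 0.87 for interferon gamma, 0.40 for phagocytosis and 2.62 for proliferation genes. None of these lists was called with an estimated correlation.

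Pig genes that changed with time were TOP2A (log2 3.34 per 24 h), PBK (3.28), PCLAF (3.15), CDK1 (3.003), KIF11 (2.86), APOA4 (-2.90), CCL16 (-2.17), CYP2A19 (-2.01), TTR (-1.90) and STC1 (-1.72). Human-table genes were NCAPG (3.48), CCNB1 (3.39), BUB1B (3.25), TOP2A (3.22), PBK (3.15), APOA4 (-2.76), CYP2A7 (-2.16), CYP2A6 (-1.99), CYP2A13 (-1.90) and STC1 (-1.76). TOP2A, PBK, APOA4 and STC1 changed at like rates in both tables, so pig reads assigned to human genes are a candidate for the human-table values. With the 48 h biopsy left out the pig CYP2A19 change was -0.45 (adjusted p = 0.48) and did not pass. In the human table the same fit gave 0.70 for CCNB1 (adjusted p = 0.932), -1.06 for CYP2A7 (0.707), -0.19 for CYP2A6 (0.969), -0.35 for CYP2A13 (0.907) and -1.48 for STC1 (0.104), so none of these changes passed without that biopsy. Without control replicate 1 or 2 the changes of the 3 CYP2A genes stayed near those of the main fit, from log2 -2.19 to -1.90. The controls do not enter the slope, so these fits are no separate check of it.

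Human-table proliferation genes rose with time, and pig reads assigned to human genes are a candidate explanation. The ratio of human-table to pig-table counts in the controls predicted a median of 81.9% of the 48 h counts over 15 members with pig-table counts (quartiles 47.8% and 85.2%). A first version that also took MKI67, CCNA2, AURKA and RRM2, which have no usable pig-table counts, at the control level gave 67.5%, and the restriction was made after that value was seen. Human dividing cells stay open for part of the change, and single genes do not decide it. PCNA had 2721 counts at 48 h against a predicted background of 774, but also 1134 against 543.8 at 12 h. At 48 h AURKB had 331 against 72.2 and PLK1 237 against 88.4. TOP2A (1981 against 1676.8) and CDK1 (1315 against 1192.1) lay nearer their background, and CCNB1 (582 against 688.3) and TPX2 (764 against 784.2) below it.

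Myeloid genes rose in the pig table, and human reads assigned to pig genes may account for some of them. Over the 7 genes that rose, the gain in pig-table counts was a median of 1.24 times the human-table count of the same gene (95% bootstrap interval over genes 0.692 to 2.09), with 4 genes above 1 in every biopsy. CD68 (212 to 542, on 3 to 9 human-table counts), CD14 (1.93 to 3.60), CD163 (1.28 to 1.73) and MSR1 (1.12 to 1.28) were above 1 in every biopsy, FCER1G (0.678 to 0.799) and S100A8 (0.00203 to 0.00833) below 1, and TYROBP (0.657 to 1.20) on both sides. For the 7 genes as a set that explanation cannot be told apart from pig expression, because the interval spans 1 and the sources do not say whether a human read given to a pig gene also counts in the human table. The T and NK cell list had 10 of 15 members lower and 1 higher, with a median of -1.43 that stayed from -1.56 to -1.28 with any library left out. This argues against more pig leukocytes of every kind. The comparison was chosen after the values were seen, however, and the list was not called with an estimated correlation (camera, adjusted p = 0.346). A change within pig macrophages stays open and untested.

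Proximal tubule genes fell in the pig table. The members fell by different factors, from log2 -3.60 for SLC5A12 to -0.62 for HNF4A, with a heterogeneity Q per degree of freedom of 9.36 over 18 genes. A lower share of proximal tubule tissue would give the same factor only if each gene were expressed evenly and in that tissue alone. That was not tested, and Q takes genes of the same libraries as independent, so the spread does not decide on this cause. Biopsies with more medulla may add a part and stay open. Of 5 thick ascending limb genes, taken from a list of 11 with a median of -0.07 (3 higher, 3 lower), 4 were above 0 with a median of 0.79, while CLDN10 fell (log2 -1.18) but did not pass without control replicate 2 (adjusted p = 0.0609). Transplantation itself and the sampling site are confounded in this design.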

How the results depend on the processing

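Fits without mitochondrial genes, gene lists with each library left out and gene families without listed or named genes were chosen after the data were seen, and the other alternatives were planned. Of the values of named genes under an alternative, 2040 kept direction and side of the threshold, 179 no longer passed, 5 newly passed and 0 reversed, and 115 of those that no longer passed had a control library left out. Scaling by DESeq2 size factors, no robust prior and limma-voom moved no count of genes past 1.5 times, nor did leaving out mitochondrial genes. With DESeq2's Wald test, pig counts were 265 lower with time, 1964 higher and 1902 lower at 24 h, and human counts 79 lower with time, 1910 and 1845 at 12 h, 1490 and 1142 at 24 h, and 2147 and 1719 at 48 h. Log2 hours gave 228 pig genes lower. A 2-fold minimum gave 1264 higher and 1171 lower in the pig xenograft comparison and 1564 lower in the human one. Without a filter, 601 human genes rose and 190 fell with time, and the median of all human-table genes in the xenograft comparison was 0.23. Scaled by the pig table, human counts were 5443 and 1712 for the xenograft, 292 and 57 with time, 6055 and 2190 at 12 h, and 6575 and 1757 at 48 h. Human genes with at most 3 control counts gave 769 higher and 0 lower, by construction of that limit. Leaving out 1 library gave 467 to 2623 higher and 726 to 2638 lower (pig xenograft), 272 to 1748 and 57 to 1059 (pig time), 1570 to 3522 and 1327 to 2870 (human xenograft), and 48 to 751 and 5 to 261 (human time), with fewer samples behind each. For the change with time, a control left out alters only the spread, and a biopsy left out leaves the spread to the control pair. Human lists called with time ranged from 6 to 12. With an estimated correlation 0 lists were called in either table for either comparison. Genes over the human background with 0 control counts were 452, 330 and 620 at 12, 24 and 48 h, and with at least 30 counts 386, 306 and 514. Apart from limits that remove genes or libraries, the cause was not tested. No paired analysis was possible because only the control libraries carry replicate numbers. With 1 biopsy per time, spread at a time was not measured, and a gene with 0 control counts allows up to 3.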

Other observations

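Of the tests in this part, the one of ribosomal protein genes was written before its values were seen, and those of solute carrier, keratin, cilia and cytochrome P450 genes were chosen after.

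Gene families were compared with all other tested pig genes by a one-sided Fisher's exact test, with adjustment over 5 families. The test takes genes as independent, although they come from the same 5 libraries, so its p-values may be too small. Solute carrier genes, which move ions and metabolites across membranes, were lower in 32.9% of 304 (100 genes) against 18.7% of 12313 others (exact p = 4.35e-09, adjusted p = 2.17e-08). Without genes on a pig list or named by the rule the shares were 30.3% of 287 and 18.6% of 12006 (exact p = 1.61e-06). In the same family 63 genes were higher, and the family median was a log2 fold change of -0.10. This family too was chosen after the values were seen, so its p-values describe the set and are no independent support. Keratin genes were higher in 83.3% of 6, namely KRT7, KRT18, KRT8, KRT14 and KRT80, with 0 lower and a median of 2.25. KRT8 and KRT18 are also on the tubular injury list, and the family was picked because members stood out, so its test carries no weight. Cytosolic ribosomal protein genes were higher in 32.7% of 49 (16 genes) against 18.4% of others, with 1 lower and a median log2 fold change of 0.41 (exact p = 0.0124, adjusted p = 0.0207). Axonemal dynein and cilia genes were lower in 25.6% of 39 against 19.0% of others, among them DNAH5 and CFAP74, with 1 higher and a median of -0.49 (exact p = 0.195). Cytochrome P450 genes were lower in 32.0% of 25 against 19.0% of others, with 3 higher and a median of -0.23 (exact p = 0.0865, adjusted p = 0.108), so with this few genes it stays open whether either family fell more often than other genes.

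Human complement regulator genes were counted in the human table. CD46 had 0 counts in both controls and 418, 257 and 570 at 12, 24 and 48 h, CD55 had 0 in both controls and 337, 234 and 246, and CD59 had 0 and 1 and then 30, 29 and 77. THBD, encoding thrombomodulin, had 2 counts in each control and 41, 27 and 36 in the biopsies. Human mitochondrial genes had 15917 and 26262 counts in the controls and 69585, 64244 and 95025 in the biopsies.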
